A study of Mus musculus with 2 samples.

How the data were processed

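Histone H3 acetylated at lysine 9 (H3K9ac), a chromatin mark found mainly at promoters of active genes, was mapped by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in mouse intestine on the day of birth. Per the labels, replicate 1 was intestine of 15 mice, replicate 2 was intestine of a pool whose number of mice is not given, both pools mixed the sexes, and fragments of 300 to 500 bp were selected. The labels number the 2 samples as biological replicates and give both the same donor entry. They form 1 group, so no groups were compared.

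The authors deposited 4 peak lists in narrowPeak format on mm10, per the README text deposited with the samples. The peaks of each replicate were called from that replicate's filtered alignments against a control. A different control was named for each replicate, an inference from the list of files each peak list was derived from. The pooled list was called from both replicates together with both controls, and the replicated list was derived from the other 3 lists, per the same README text. The aligner, the peak caller, its threshold and the rule that made the replicated list are not given in the sources used here. The controls and the alignments were not analysed here.

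For each peak the deposited lists give a fold enrichment over the control, which is a linear ratio made by the authors and belongs to the peak, and it was used to describe, rank or filter peaks within a list and, for overlapping peaks of the replicates, to describe how far their values differed, with no test. The deposited lists also give the −log10 of a p-value and of a q-value for each peak, made by the authors. Read depth is unknown, because the peak lists hold no read counts, so no interval that needs depth is given. Each list had been filtered by the authors, so a gene without a listed peak is one without a called peak, which is not a measurement of no acetylation. The lists hold 0 per-sample columns that could not be assigned.

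Positions are in mm10 and were written counting from 1. Every peak end lay within the chromosome lengths of the GRCm38 reference. Genes, transcripts and exons were taken from GENCODE release M21, with 21938 protein-coding genes and 93513 transcription start sites (TSSs) of those genes among 55413 annotated genes. A protein-coding gene was called marked where a peak of the replicated list lay within 1000 bp of any of its TSSs. Replicated peaks were merged into domains across gaps of up to 1000 bp, and a gene's domain was the widest within 1000 bp of a TSS. A distal peak lay more than 10000 bp from any annotated TSS. Peaks on scaffolds outside the chromosomes were counted and were left out of comparisons with genes.

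Overlap between the replicates required 1 bp and was compared with 1000 circular shifts of the other list within each chromosome, in a one-sided permutation test whose smallest possible p is 0.000999. The same shifts were used for the share of peaks at promoters. Agreement of fold enrichment was described by Spearman's rho and Pearson's r of log2 values over overlapping peaks, each replicate 1 peak being paired with its best overlapping peak of replicate 2. Gene lists were compared with all other protein-coding genes by two-sided Fisher's exact tests, adjusted over 31 lists by the Benjamini-Hochberg method. Median domain widths of lists with at least 5 marked members were compared with 100000 random lists of marked genes of the same size, in two-sided permutation tests adjusted in the same way. X-linked genes were compared with autosomal genes by a two-sided Fisher's exact test. Shares of peaks have 95% exact binomial intervals in which each peak counts as independent. Genes and peaks are not replicates, so these p-values describe the deposited lists.

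The 31 gene lists, the tests described above and the alternatives were fixed before the data were examined, and tests chosen later are named as such in the closing section. The lists were enterocyte, suckling-stage enterocyte, adult-stage enterocyte, goblet cell, Paneth cell, enteroendocrine cell, tuft cell, crypt stem and progenitor cell, intestinal epithelial transcription factor, epithelial junction and keratin, smooth muscle, interstitial cell of Cajal, enteric neuron and glia, gut mesenchyme, endothelium, immune cell, erythroid cell, mesothelium, liver, exocrine pancreas, stomach, striated muscle and heart, brain neuron, lung and kidney, epidermis, germ cell, housekeeping, cell cycle, Hox clusters, olfactory receptors and cytosolic ribosomal proteins. They were written from textbook knowledge, and 3 of them were defined by a pattern in the gene symbol. Of the 417 symbols written out for the other lists, 415 were found in the annotation.

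Genes and peaks are named by a fixed rule. It takes the 10 protein-coding genes with the highest promoter fold enrichment in the replicated list and a peak in both replicates, the 10 with the widest promoter domains, and in each list up to 4 marked members with the widest domains and up to 4 unmarked members in alphabetical order. It also takes the 5 strongest distal peaks and the 3 strongest peaks of each replicate that overlapped no peak of the other. Genes named outside the rule are identified where they appear.

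The CpG ratio of a promoter is the observed over expected CpG content within 500 bp of the outermost annotated TSS of the gene. Gene lists were compared with 10000 random lists matched over 10 bins of that ratio, and again with the ratio of the TSS that has the highest value.

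Alternatives were stricter q-values (−log10 q of at least 2 or 5), overlap of at least 50%, the list of 1 replicate or of the pooled replicates in place of the replicated list, promoter windows of 500 or 2500 bp, merging gaps of 500 or 3000 bp, and all annotated genes as the background. Scripts were written in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

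The code was tested on simulated data. The overlap code returned the brute-force answer in 200 of 200 trials. The shift test called 0 of 20 unrelated lists and 20 of 20 lists that shared planted peaks. Over 21938 simulated genes, the gene list test called 85 of 120 lists with raised marking, 118 of 120 lists with lowered marking and 4 of 380 unchanged lists. Simulated marking did not depend on the CpG ratio of the promoter, as marking in the data did, so these rates need not hold for the lists tested here. The width test called 75 of 120 lists with doubled widths and 2 of 354 unchanged lists.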

Results

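In the intestine of newborn mice, the replicated H3K9ac peaks lay mainly at promoters. Of the gene lists compared, those of enterocytes, epithelial junctions and gut transcription factors had a replicated peak at 90.9% or more of their promoters. So did the lists of gut mesenchyme, housekeeping, cell cycle and ribosomal protein genes. The list of adult-stage enterocyte genes had a replicated peak at 2 of 10 and a peak in the replicate 1, replicate 2 and pooled lists at 5, 4 and 6 of 10. Paneth cell genes had a called peak at 0 of 13 promoters in the replicated list and at 1 of 13 in the pooled list, and enteroendocrine genes at 1 of 20 and 7 of 20. In the replicated list the adult-stage and Paneth shares lay within the ranges of lists matched on promoter CpG ratio, which began at 10% and 0.0%. H3K9ac ChIP-seq was done on 2 biological replicates, each a pool of intestines of newborn mice. The replicate 1 list held 40241 peaks with a median width of 332 bp, covering 0.842% of the genome. The replicate 2 list held 44083 peaks with a median width of 311 bp, covering 0.858%. The pooled list held 52220 peaks and the list of replicated peaks held 22580, with a median width of 797 bp. The lowest −log10 q was 0.219 in replicate 1, 0.304 in replicate 2, 0.28 in the pooled list and 0.431 in the replicated list. The medians were 2.93, 2.59, 2.93 and 12.3. The replicate and pooled lists thus hold many weak peaks, and a gene with a peak only there can rest on one of them. Read depth is unknown, since the lists give no counts. Fold enrichment is the authors' value for each peak.

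The first question was whether both pools of mice carried the mark at the same regions. The promoters of Clk1, a kinase that phosphorylates splicing factors, of Kmt5b, a histone methyltransferase, and of Rbm39, a splicing factor, were among the strongest in the replicated list and had strong peaks in each replicate. The rule that named these genes required a peak in both replicates, so they illustrate shared peaks and do not answer the question. At Clk1 the fold was 38.0 in replicate 1 and 30.8 in replicate 2, at Kmt5b 38.2 and 26.4, and at Rbm39 39.3 and 24.8. Peaks that were found in 1 replicate and not in the other reached lower folds than these. The strongest of them in replicate 1 lay at the promoter of Rad9b (chromosome 5, 122353811 to 122354226), with a fold of 8.25. In replicate 2 it lay at the promoter of Ndufs8 (chromosome 19, 3912000 to 3912796), a subunit of respiratory complex I, with a fold of 9.24. Both folds were above the median of peaks with a partner, 5.73 in replicate 1 and 5.32 in replicate 2.

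Of the replicate 1 peaks, 21987 (54.6%) overlapped a replicate 2 peak, against a mean of 1.88% and a maximum of 3.26% over 1000 circular shifts (permutation p = 0.000999, the smallest these shifts can give). Of the replicate 2 peaks, 22652 (51.4%) overlapped a replicate 1 peak, against a mean of 1.73% and a maximum of 3.13% (permutation p = 0.000999). The shifts do not keep peaks at promoters of protein-coding genes, where 52.1% of replicate 1 peaks and 48.3% of replicate 2 peaks lay. Overlap beyond the shifts can therefore come in part from a location at promoters that lists of this mark share. The overlap followed the strength of the peak. Among peaks with a −log10 q under 2, 21.1% of replicate 1 peaks (95% interval 20.3 to 21.9) and 20.8% of replicate 2 peaks (20.1 to 21.4) had a partner. At 10 or more, 99.8% (99.7 to 99.9) and 99.9% (99.8 to 99.97) had one. The median fold of peaks with a partner was 5.73 in replicate 1 and 5.32 in replicate 2, and that of peaks without one was 3.33 and 3.23. The other unpartnered peaks named by the rule lay near Acsl1 (chromosome 8, 46446547 to 46447191, intergenic, fold 7.90) and in an intron of Clint1 (chromosome 11, 45854979 to 45855658, 7.73) in replicate 1. In replicate 2 they lay at the promoters of Chrna7, a nicotinic receptor subunit (chromosome 7, 63212080 to 63212565, 8.48), and Plekhg3 (chromosome 12, 76531886 to 76532257, 8.18).

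Across the 21987 overlapping pairs, the log2 fold of the replicates had a Spearman's rho of 0.708 and a Pearson's r of 0.732. The correlation is across peaks, which are not independent replicates. The difference between the replicates had a median of 0.03 and an SD of 0.60 on the log2 scale. A replicate 2 peak was counted again for each replicate 1 peak paired with it, so this spread can come in part from the pairing. With a reciprocal overlap of 50%, 15180 pairs had a rho of 0.836, a median difference of 0.11 and an SD of 0.47. Fold values of a single peak that differ by less than these spreads were not told apart. No peak had the same coordinates in both replicates (0 of 40241).

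**Figure D1:**
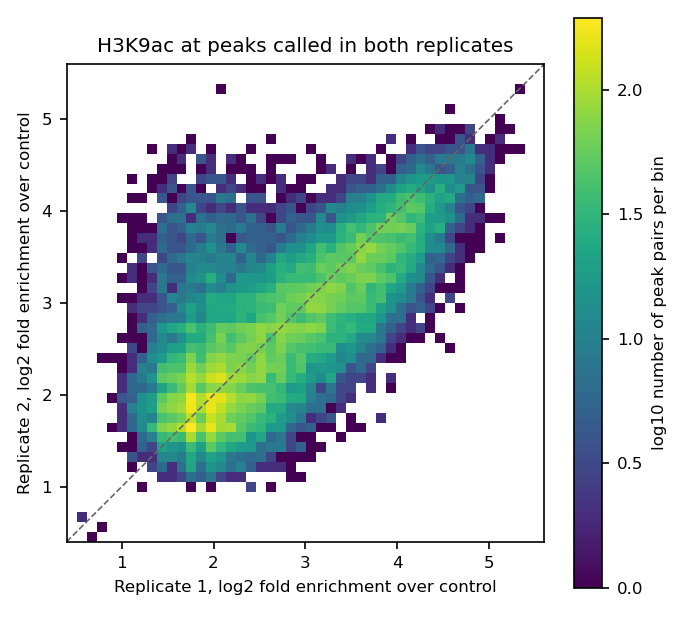
Log2 fold enrichment over control of 21987 overlapping peak pairs, replicate 1 on the horizontal axis and replicate 2 on the vertical axis, with the colour of each bin giving the log10 number of pairs and the dashed line marking equal values. Most pairs lie along the line (Spearman's rho 0.708), and a group of pairs above it has a high value in replicate 2 and a low one in replicate 1. A replicate 2 peak is counted again for each replicate 1 peak paired with it, so this group can come in part from the pairing.

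The replicated list drew on the stronger peaks. Every one of its 22580 peaks stood in the pooled list with the same coordinates, and they made up 43.2% of it. The median fold was 5.94 for pooled peaks that were in the replicated list and 2.91 for the 29640 that were not, and the median widths were 797 and 233 bp. Of the replicated peaks, 19084 (84.5%) overlapped a peak in both replicates, 1943 overlapped one in replicate 1 alone, 1363 in replicate 2 alone and 190 in neither. The peaks that overlapped both had a median fold of 7.15 and the others 3.6. All 18970 pooled peaks that shared at least 50% of either peak's length with a peak in each replicate were in the replicated list.

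The 10 genes with the highest promoter fold were Clk1 (chromosome 1, 58422872 to 58424272, fold 42.3), Bicral, Kmt5b, Tnpo1, Ywhaz, Csnk1g3, Pnrc1, Ubc with Gm10382, and Rbm39 (fold 37.1). Tnpo1 encodes a nuclear import receptor and had a fold of 39.9. Ubc encodes polyubiquitin, and the peak it shares with Gm10382 had a fold of 37.8. The Clk1 peak covered the TSS, part of the 5′ UTR and intron, and flanking sequence outside the gene. At Bicral the fold was 40.6 in the replicated list, 23.3 in replicate 1 and 33.6 in replicate 2, and at Pnrc1, a nuclear receptor coactivator, it was 37.9, 22.6 and 30.8.

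Of the 22575 replicated peaks on chromosomes, 16017 (70.9%) lay within 1000 bp of the TSS of a protein-coding gene, against a mean of 5.67% and a maximum of 7.12% over 1000 shifts (permutation p = 0.000999), a ratio of 12.5. They had a median width of 1025 bp and a median fold of 8.14. Introns held 2827 peaks (12.5%, median fold 3.85), intergenic sequence 1904 (8.43%, 4.08), exons 919 (4.07%) and promoters of other annotated genes 908 (4.02%). Among the 1000 peaks with the highest fold, 988 lay at promoters of protein-coding genes. The share at promoters was 52.1% in the replicate 1 list, 48.3% in the replicate 2 list and 43.2% in the pooled list. In all, 13056 of 21938 protein-coding genes (59.5%) were marked, and with the list of replicate 1 or of replicate 2 alone the number was 13509 or 13481.

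The next question was which cell types of the intestine were represented among the marked genes. The lists name cell types, but a listed gene can be active in other cells too, and the cells that carried a peak were not measured. The enterocyte list had a called peak at 21 of 22 promoters, all but Myo1a, a brush border myosin. All 12 genes of the suckling-stage enterocyte were marked, among them Naga and Neu1, lysosomal hydrolases, and Prdm1, a transcriptional repressor of the fetal and suckling epithelium. Of 22 intestinal transcription factors 20 were marked, with Cdx2 and Gata6 in the widest domains, and the 15 genes of epithelial junctions and keratins were marked without exception. In the wall around the epithelium, 19 of 20 genes of the gut mesenchyme and 14 of 16 genes of smooth muscle were marked.

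Against a background of 59.5%, the enterocyte list (95.5%) was marked more often than other protein-coding genes in Fisher's exact test (adjusted p = 0.000684). Fisher's exact test also called the suckling-stage list (100%, adjusted p = 0.00380), the transcription factors (90.9%, adjusted p = 0.00318) and the junction and keratin list (100%, adjusted p = 0.00142). Of the tissue around it, the exact test called the gut mesenchyme (95%, adjusted p = 0.00150) and smooth muscle (87.5%, adjusted p = 0.0275). Apoa1 and Apoc3, neighbouring apolipoprotein genes, had promoter folds of 9.70 and 9.01 in the replicated list. At Mttp, which loads lipid onto lipoproteins, the fold was 11.8, with 11.3 in replicate 1 and 11 in replicate 2. At Rbp2, the retinol-binding protein of enterocytes, it was 9.85, with 7.90 and 8.78. Cdx2, the homeobox factor of intestinal identity, had a fold of 19.9 (18.2 and 17.0 in the replicates), and Epcam, an epithelial adhesion molecule, 19.0 (17.5 and 18.1). Srf, a regulator of smooth muscle genes, had 22.6 (19.9 and 19.4). The unmarked transcription factors were Ehf and Foxa2, each with a peak in the pooled list at a fold of 3.12. The unmarked smooth muscle genes were Cnn1 and Kcnmb1, and the unmarked mesenchymal gene was Lum. Cnn1 had a peak in replicate 1 (fold 4.05), replicate 2 (2.27) and the pooled list (3.88), and Kcnmb1 had one in replicate 2 alone (3.23). With a −log10 q of at least 5, the call on smooth muscle (62.5%, adjusted p = 0.802) and that on the mesenchyme (80.0%, adjusted p = 0.0528) were lost in the exact test. The smooth muscle call was also lost with promoter windows of 500 bp (75.0%, adjusted p = 0.238) and 2500 bp (87.5%, adjusted p = 0.0526), all in Fisher's exact test.

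Nearly all housekeeping, cell cycle and ribosomal protein genes were marked. All 16 housekeeping genes (Fisher's exact adjusted p = 0.000939) and all 17 cell cycle genes (adjusted p = 0.000603) were marked, the latter including Mki67 and Aurka. Of 83 genes of cytosolic ribosomal proteins 80 were marked (Fisher's exact adjusted p = 1.09e-13), and the exceptions were Rpl10l, Rpl39l and Rpl3l. The central 95% of random lists matched on promoter CpG ratio reached up to 100% for the cell cycle list, 93.8% for housekeeping and 92.8% for ribosomal protein genes. With the ratio of the highest TSS it reached up to 100% for the cell cycle and housekeeping lists and 97.6% for ribosomal protein genes.

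Genes of secretory epithelial cells had few peaks in the replicated list. None of 13 Paneth cell genes was marked, among them Ang4 and the defensins Defa17, Defa22 and Defa24. How well reads could be placed at these genes was not examined, so the lack of a called peak there does not show a lack of acetylation. Of 20 enteroendocrine genes 1 was marked, Sct, the gene of the hormone secretin, with a fold of 7.69 in the replicated list, 7.0 in replicate 1 and 6.46 in replicate 2. Of 14 goblet cell genes 4 were marked, Klf4, Creb3l1, Galnt12 and Creb3l4, while Agr2, Atoh1, Clca1 and Ern2 were among the unmarked. Of 13 tuft cell genes 3 were marked, Ptgs1, Pou2f3 and Hck. Of 10 genes of the adult-stage enterocyte 2 were marked, Slc2a2, a glucose transporter, with a fold of 5.11, and Apobec1, which edits Apob mRNA, with 9.61.

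Each of these lists was marked less often than other protein-coding genes in Fisher's exact test, with adjusted p-values of 3.46e-05 for Paneth cells, 4.01e-06 for enteroendocrine cells, 0.0316 for goblet cells, 0.0144 for tuft cells and 0.0255 for the adult-stage enterocyte. Promoters of low CpG content were seldom marked at all, 5.47% in the lowest of 10 bins of the CpG ratio against 96.5% in the highest, and the median ratio was 0.137 in the Paneth cell list and 0.548 in the enteroendocrine list. The Paneth, goblet, tuft and adult-stage lists each lay within the range of random lists matched on that ratio. The Paneth range began at 0.0%, so that list could not have fallen below it. In the pooled list the calls were lost for goblet cells (57.1%, Fisher's exact adjusted p = 0.626), tuft cells (46.2%, adjusted p = 0.292) and the adult-stage enterocyte (60%, adjusted p = 0.752). With replicate 1 or replicate 2 alone they were lost for goblet cells (42.9% and 50%) and the adult-stage enterocyte (50% and 40%), and with replicate 2 alone for tuft cells (38.5%). The enteroendocrine list was called lower in each list, but with 4 of 20 genes marked in replicate 1 alone, 5 of 20 in replicate 2 alone and 7 of 20 in the pooled list (Fisher's exact adjusted p = 0.00107, 0.00447 and 0.0156). Pooled peaks outside the replicated list had a median fold of 2.91, against 5.94 for the others. Genes gained in the pooled list can therefore rest on weak peaks.

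Other cell types of the gut wall differed. Genes of enteric neurons and glia were marked at 7 of 22 promoters (Fisher's exact adjusted p = 0.0207), with Hand2, a transcription factor of enteric neuron development, at a fold of 8.89 and Erbb3, a receptor of glial cells, at 11.5. Immune cell genes were marked at 1 of 16 promoters, that of Ikzf1 (adjusted p = 4.92e-05), or at 4 of 16 in each replicate alone and in the pooled list, and mesothelial genes at 1 of 7, that of Bnc1 (Fisher's exact adjusted p = 0.0260). The other 5 lists did not pass the test. They were crypt stem and progenitor cells (12 of 16 marked, Fisher's exact adjusted p = 0.330), interstitial cells of Cajal (5 of 6, adjusted p = 0.425), endothelium (8 of 15, adjusted p = 0.611, or 11 of 15 in each replicate list and 13 of 15 in the pooled list, above the background and not called), erythroid cells (4 of 12, adjusted p = 0.0913) and the Hox clusters (27 of 39, adjusted p = 0.282). In the stem and progenitor list, Lrig1 (fold 17.3), Rnf43 (9.81), Myc (11.5) and Sox9 (8.14) were marked, and Ascl2, Lgr5, Olfm4 and Smoc2 were not. Of these unmarked genes, Smoc2 had a peak in replicate 1 (fold 3.78), replicate 2 (4.67) and the pooled list (4.325). Ascl2 had one in the pooled list alone (2.61), and Lgr5 and Olfm4 had none in any list. Among the interstitial cell genes, Kit, the receptor that marks these cells, had a fold of 5.53 and Ano1, their chloride channel, 4.57. With all annotated genes as the background, of which 29.2% were marked, the stem and progenitor, interstitial cell and Hox lists were called higher, and neuron and glia genes were no longer lower. The calls on neuron and glia genes (54.5%, Fisher's exact adjusted p = 0.432) and on mesothelial genes (57.1%, adjusted p = 0.729) were lost in the pooled list, and in the replicate 1 list (45.5%, adjusted p = 0.154, and 28.6%, adjusted p = 0.149). The mesothelial call was also lost at a −log10 q of at least 5, with 2500 bp windows and against all annotated genes.

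Genes of other organs were marked at few promoters in the replicated list. None of 13 exocrine pancreas genes and none of 13 stomach genes were marked there (Fisher's exact adjusted p = 3.46e-05 each), nor any of 16 genes of lung and kidney (adjusted p = 4.01e-06). In the replicate 1, replicate 2 and pooled lists the pancreas had 3, 0 and 4 marked genes, the stomach 1, 2 and 1, and lung and kidney 0, 2 and 4, and these calls held in each. Striated muscle and heart genes had 3 of 15 in each of those peak lists, germ cell genes had 1, 3 and 2 of 14, and brain neuron genes had 4, 1 and 5 of 14. Of 14 liver genes 2 were marked, Apoh and Ttr (Fisher's exact adjusted p = 0.00142). Striated muscle and heart had 1 of 15, Ckm (Fisher's exact adjusted p = 0.000102), and brain neurons 2 of 14, Slc6a3 and Slc17a7 (adjusted p = 0.00142). Epidermis had 2 of 12, Krt1 and Krt10 (Fisher's exact adjusted p = 0.00789), and germ cells 1 of 14, Dazl (adjusted p = 0.000212). Of 1135 olfactory receptor genes 1 was marked, Olfr56, with a p that fell below what double precision holds. The replicate 1, replicate 2 and pooled lists had a peak at 1, 6 and 4 of these genes. Across the 31 lists, 9 were marked more often, 17 less often and 5 were not called. Of the 9, 8 lay above the central 95% of lists matched on the CpG ratio, and 6 with the ratio of the highest TSS. Of the 17, 9 lay below it with either ratio, and the other 8, which include the immune, mesothelium, liver and epidermis lists, lay within it. For the Paneth list with either ratio, and for epidermis with the first, that range began at 0.0%, so neither could have fallen below it. Against all annotated genes, the calls on liver, striated muscle and heart, brain neuron, epidermis, germ cell and immune genes were lost, and the brain neuron call was also lost in the pooled list (35.7%, Fisher's exact adjusted p = 0.0677).

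**Figure D2:**
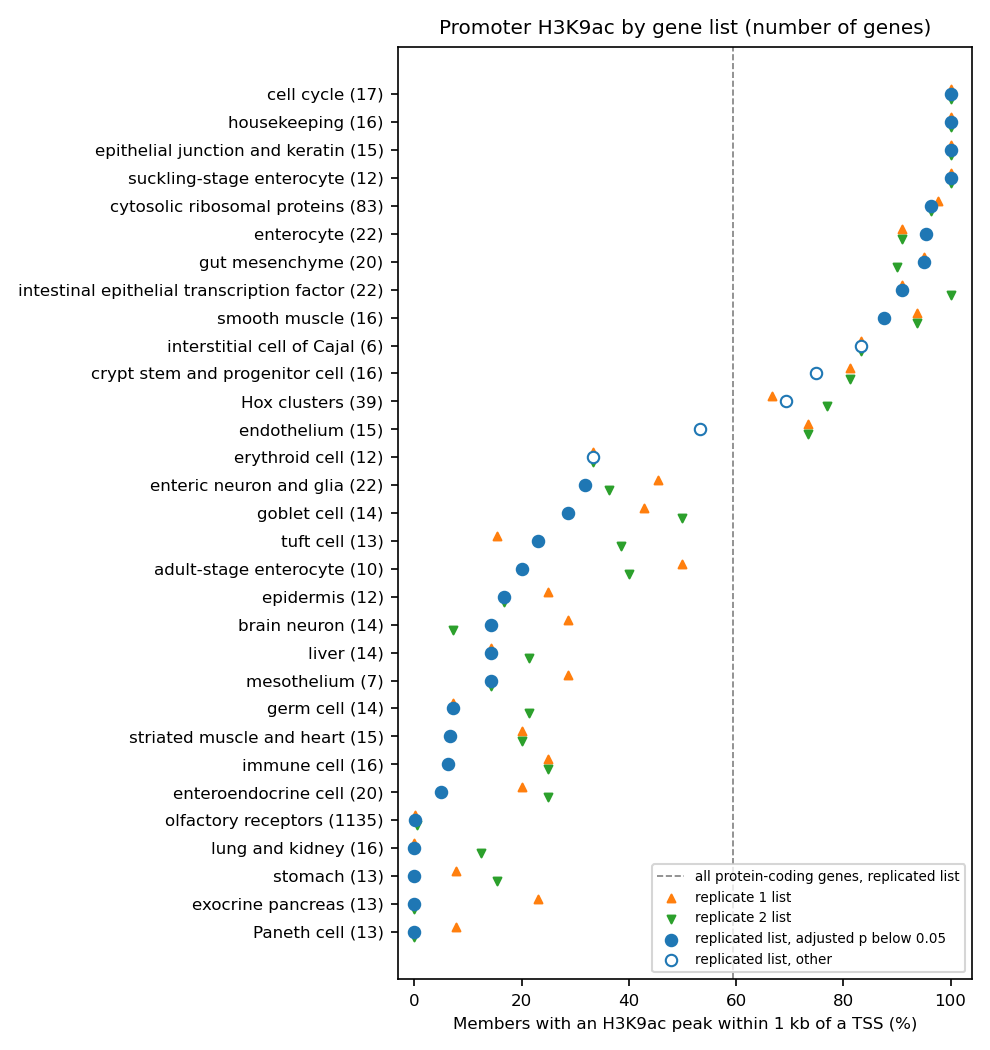
Share of the members of each gene list with an H3K9ac peak within 1000 bp of a TSS, in percent, with the number of members in brackets. Circles give the replicated list, filled where the adjusted p was below 0.05, triangles give each replicate's own list, and the dashed line gives all protein-coding genes (59.5%). The enterocyte list stands at 95.5% and the Paneth cell list at 0.0%.

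The breadth of the acetylated region was compared next. The widest promoter domains lay at Tnrc18 (12948 bp, chromosome 5, 142811366 to 142824313), at Foxf1, a transcription factor of the gut mesenchyme (12414 bp, chromosome 8, 121078854 to 121091267), and at Gata6, a transcription factor of the gut endoderm (12052 bp, chromosome 18, 11047695 to 11059746). Wsb2 (11286 bp), Nkx2-3, a homeobox gene of the gut mesenchyme (11116 bp), Eps8l3 (10617 bp), Meis2 (10110 bp), Zfp503 (10093 bp), Irf2bp2 (9584 bp) and Cdx2 (9530 bp) followed. The Cdx2 domain ran from 147299357 to 147308886 on chromosome 5 and spanned the whole gene from its TSS to its 3′ end. Transcription factors of the intestinal epithelium had a median domain of 4263 bp, against 1521 bp for all marked protein-coding genes.

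In permutation tests against 100000 random lists, 6 of 14 lists had wider domains in the replicated list and 0 had narrower ones. The wider ones were the epithelial transcription factors (adjusted p = 0.00014), the cytosolic ribosomal proteins (median 2133 bp, adjusted p = 0.00014), the gut mesenchyme (2415 bp, adjusted p = 0.00635), the stem and progenitor list (2375 bp), the junction and keratin list (2315 bp) and the Hox clusters (2083 bp), the last 3 with a permutation adjusted p of 0.0256. Onecut2 (7415 bp) and Elf3 (6756 bp) led the transcription factors after Gata6 and Cdx2, Ptch1, the Hedgehog receptor, had 7952 bp and Zeb2 7171 bp in the mesenchyme, and Rps2 had 5159 bp among the ribosomal proteins. Epcam had 4604 bp and Cldn3 3689 bp among junction genes, and Lrig1 had 5110 bp and Rnf43 4348 bp among stem and progenitor genes. Enterocyte genes had a median of 1602 bp and did not pass the permutation test (adjusted p = 0.726). They were called wider in the replicate 1 list (2146 bp, permutation adjusted p = 0.0225), the replicate 2 list (2054 bp, 0.0423) and the pooled list (3581 bp, 0.000133), and in the replicated list Apoa1 and Apoc3 shared a domain of 7863 bp (chromosome 9, 46228025 to 46235887). The suckling-stage list (1981 bp, permutation adjusted p = 0.187), housekeeping genes (2018 bp, 0.134), cell cycle genes (1916 bp, 0.187), smooth muscle (1736 bp, 0.511), enteric neuron and glia (1795 bp, 0.531), endothelium (1071 bp, 0.187) and interstitial cells of Cajal (908 bp, 0.187) did not pass either. Neuron and glia genes were called narrower in the replicate 1 list (459 bp, permutation adjusted p = 0.00154), and endothelium in the replicate 2 list (750 bp, 0.0425) and with merging across 500 bp (795 bp, 0.031). Smooth muscle was called wider in the pooled list (3481 bp, 0.0004). Some lists with too few marked members for that test were called narrower elsewhere, as in the pooled list for adult-stage (289 bp), enteroendocrine (310.0 bp), tuft (300.0 bp), brain neuron (367 bp) and erythroid genes (605 bp), with permutation adjusted p-values of 0.00048, 0.000711, 0.00055, 0.00673 and 0.0374. Some of these genes, such as 6 of the 7 enteroendocrine ones, were marked only by pooled peaks outside the replicated list. Such peaks had a median width of 233 bp, against 797 bp for the others, so these calls can follow from how the genes entered the lists. Neighbouring genes can share a domain, as Hoxb3 and Hoxb4 did, and the Hox median fell below that of all marked genes in the replicate 2 list (1216 against 1417 bp), while at a −log10 q of at least 5 the Hox and junction calls were lost (permutation adjusted p = 0.162 and 0.0568). With merging across 3000 bp, enterocyte genes (3332 bp, permutation adjusted p = 0.00014), smooth muscle, housekeeping and suckling-stage genes were also called wider and the stem and progenitor list was not. The stem and progenitor call was also lost in the pooled list (permutation adjusted p = 0.0739), and the Hox call with merging across 500 bp (1571 bp, 0.681).

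**Figure D3:**
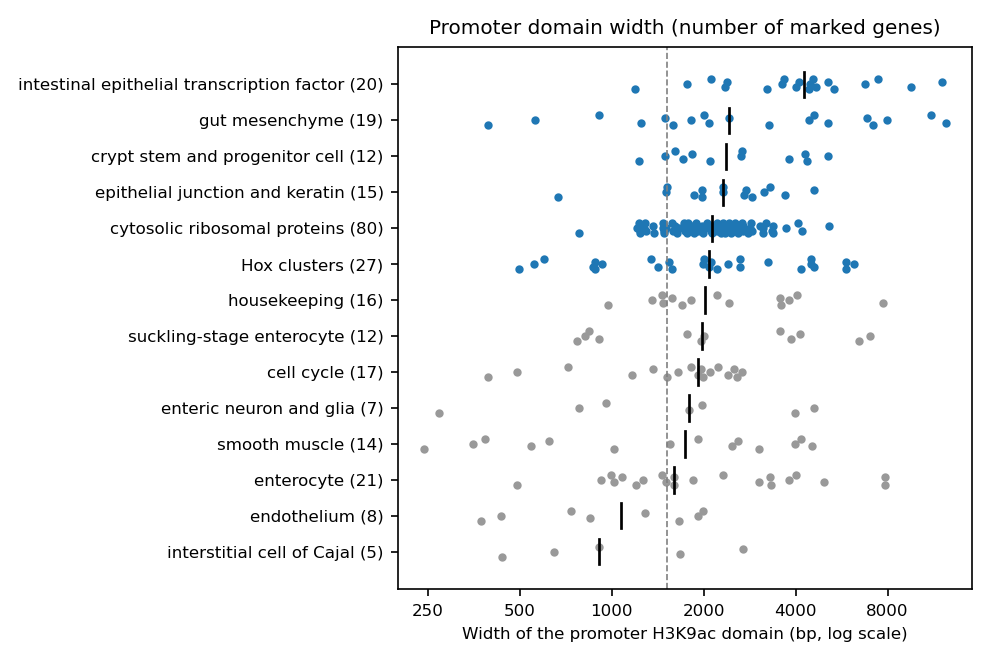
Width of the promoter H3K9ac domain in bp on a log scale for the marked members of each list, with the number of marked members in brackets. Each point is a gene, black bars are list medians, the dashed line is the median of all marked genes (1521 bp), and blue points belong to the 6 lists that passed the permutation test. The transcription factors have a median of 4263 bp.

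**Figure D4:**
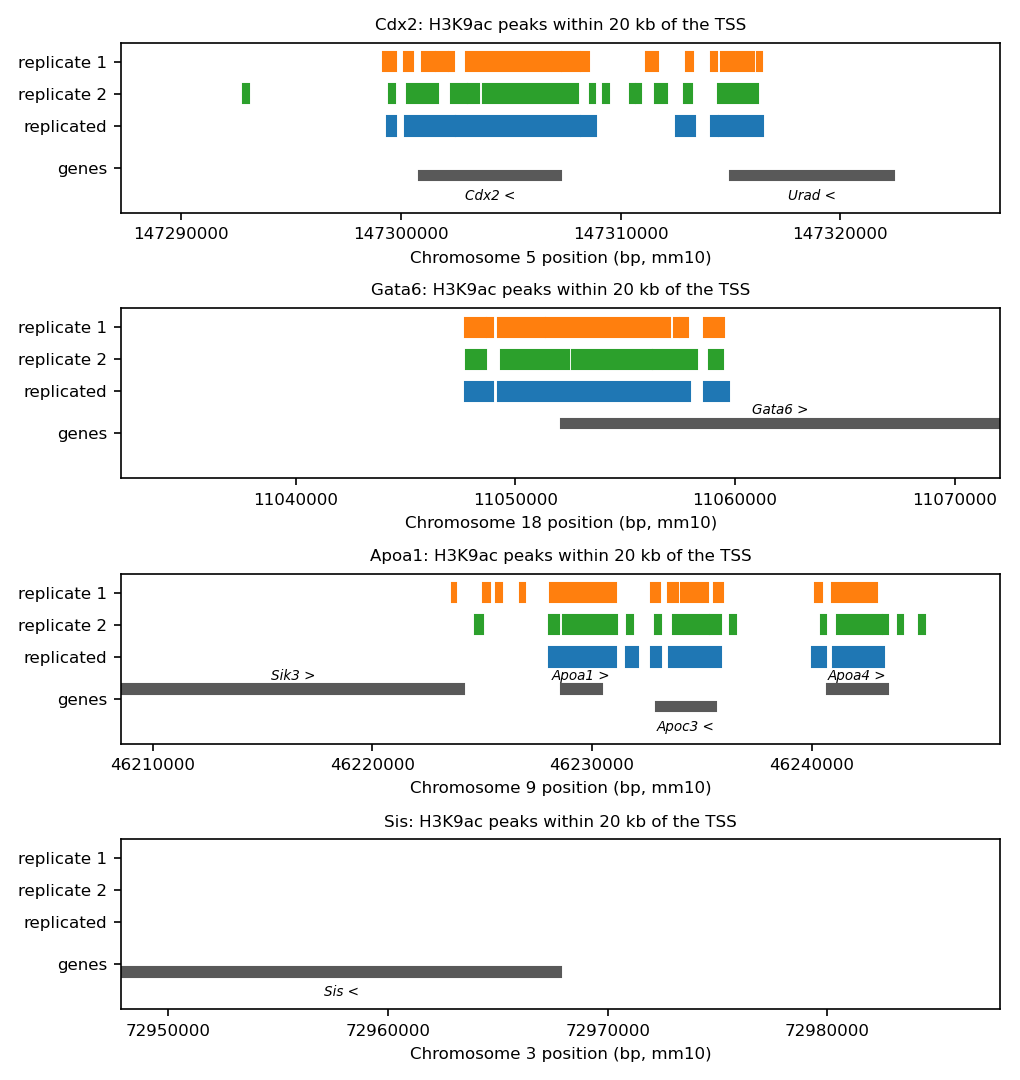
Peaks of replicate 1, replicate 2 and the replicated list within 20000 bp of the TSSs of Cdx2, Gata6, Apoa1 and Sis, with protein-coding genes drawn in grey and their direction shown by an arrowhead; the horizontal axis is the position in bp on mm10. Peaks of each list cover Cdx2, the start of Gata6 and the Apoa1, Apoc3 and Apoa4 genes, while 0 peaks lie around Sis, the sucrase-isomaltase gene, which was added after its values were seen.

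Genes on the X chromosome were marked less often than autosomal genes in these pools of both sexes. Of 948 X-linked protein-coding genes 348 (36.7%) were marked, against 12705 of 20807 autosomal genes (61.1%; Fisher's exact p = 2.1e-49). In random lists of all genes matched to the X-linked genes in promoter CpG ratio, a median of 49.8% were marked, with 95% of lists between 47.5% and 52.2%. Read depth on the X chromosome is unknown, so whether peaks were harder to call there was not examined.

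Few replicated peaks lay far from any TSS. The strongest distal peak lay 23515 bp from Wnt10a, a Wnt ligand gene, in intergenic sequence (chromosome 1, 74816878 to 74817544), with a fold of 16.9 in the replicated list, 14 in replicate 1 and 13.4 in replicate 2. The next lay 23946 bp from Smad7, an inhibitor of TGF-beta signalling (chromosome 18, 75342179 to 75343583, intergenic), with folds of 15.6, 10.6 and 14.1. A pair of intergenic peaks lay nearest to Chd7, a chromatin remodeller, at 41480 bp (chromosome 4, 8646809 to 8648926, fold 15.4) and 55848 bp (chromosome 4, 8911079 to 8912006, fold 15.2). The fifth lay in an intron of an annotated gene, 62606 bp from Ppara (chromosome 15, 85669995 to 85672377, fold 14.2). In all, 1697 peaks (7.52%) lay more than 10000 bp from any annotated TSS, with a median fold of 3.86 and a median width of 434 bp, and 750 of them lay within protein-coding genes. A nearest gene is a position and was not tested as a target.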

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

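The tests on the Paneth, goblet and tuft cell lists without the enteroendocrine list, those with the CpG ratio of the highest TSS, and the CpG matching of single lists and of X-linked genes were chosen after the results were seen. Replicated peaks on scaffolds outside the assembled chromosomes, which entered no comparison, numbered 5, with folds of 12.7, 2.75, 5.53, 3.98 and 6.21. The design holds 1 group, so no explanation was tested by comparing groups.

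The 6 lists of enterocyte, suckling-stage, transcription factor, junction, smooth muscle and mesenchyme genes together were marked at 101 of 107 promoters (94.4%). A high CpG content of these promoters was weighed first, since marking rises with the CpG ratio. Of 10000 lists matched on that ratio the central 95% reached up to 62.6%, and up to 66.4% with the ratio of the highest TSS, which argues against CpG content as the whole cause. Each of the 6 lists also lay above its own matched range. The cell types in the tissue were not measured, so how much each contributed stays open.

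The Paneth, goblet, enteroendocrine and tuft cell lists were marked at 8 of 60 promoters (13.3%). CpG content as the whole cause of this low share was argued against by the matched lists, whose central 95% began at 31.7%. That result rests largely on the enteroendocrine list, marked at 5.0% against a matched range of 40 to 75%. For the other 3 lists CpG content as the whole cause stays open. Their 17.5% lay below the 20% where the central 95% of matched lists began but not below the 17.5% obtained with the highest TSS. Each alone lay within its own range, but that of the Paneth list began at 0.0%, so that list could not have fallen below it. A second candidate, acetylation in too few cells to reach the replicated list, also stays open, because 14 of 52 unmarked members (26.9%) gained a peak in the pooled list against 15 of 103 for other organs (14.6%; one-sided Fisher's exact p = 0.0519). How well reads could be placed at the genes of these lists was not examined.

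Peaks called in 1 replicate and not in the other numbered 18254 of 40241 in replicate 1 and 21431 of 44083 in replicate 2. Weak enrichment near the calling threshold may account for most of them, since 4.41% of replicate 1 peaks and 2.62% of replicate 2 peaks with a −log10 q of at least 5 lacked a partner of any strength, where up to 10% had been set as the bound. With both lists limited to a −log10 q of at least 5, 81.5% and 89.9% had a partner. The bound was not set for that setting. For a GC bias that differs between the libraries, the bound was a difference of 2 percentage points in the median GC content of unpartnered peaks. The difference was 1.04 (bootstrap 95% interval 0.919 to 1.16), with 50.59% in replicate 1 and 49.55% in replicate 2, so the bound was not reached. The interval excludes equal medians, and peaks with a partner had 57.13% and 57.09%, so a smaller GC bias stays open. Sequencing depth is unknown and stays open.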

How the results depend on the processing

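All alternatives were chosen before the data were examined, and the cause of a change was not tested unless stated. The replicates overlapped beyond the shifts, promoters held more peaks than the shifts, and X-linked genes were marked less often than autosomal genes in each alternative run. The marking calls on the enterocyte, suckling-stage, transcription factor, junction, housekeeping, cell cycle, ribosomal, Paneth, enteroendocrine, pancreas, stomach, lung and kidney, and olfactory lists also held in each. Some calls ended with the share of the list the same, because the background or the adjusted p moved. No paired analysis was possible because there is 1 group.

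Spearman's rho was 0.836 with a reciprocal overlap of 50% and 0.669 with −log10 q of at least 5. The share of replicated peaks that overlapped both replicates was 64.8% with 50% of the peak's length, 85.2% with −log10 q of at least 2 and 95.4% with at least 5.

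For marking at −log10 q of at least 5, calls ended for goblet cells (28.6%), smooth muscle (62.5%), mesenchyme (80.0%) and mesothelium (14.3%), and erythroid genes (16.7%) became called lower. With 1 replicate left out, the range was 40 to 50% for the adult-stage enterocyte and 42.9 to 50% for goblet cells, neither called. Tuft cells were not called without replicate 1 (38.5%; 15.4% without replicate 2), nor neuron and glia (45.5%; 36.4% without replicate 1) and mesothelium (28.6%; 14.3%) without replicate 2. Endothelium was at 73.3% in both, above the background and not called. In the pooled list, calls ended for the adult-stage enterocyte (60%), goblet (57.1%), tuft (46.2%), neuron and glia (54.5%), mesothelium (57.1%) and brain neuron (35.7%), and endothelium turned higher, uncalled (86.7%). With windows of 500 bp smooth muscle was not called (75.0%) and erythroid genes were (25%). With 2500 bp the adult-stage enterocyte (30.0%), goblet (35.7%), tuft (30.8%), smooth muscle (87.5%) and mesothelium (28.6%) were not called. Against all annotated genes the shares stayed and the background fell to 29.2%, which ended the calls on the adult-stage enterocyte (20%), goblet (28.6%), tuft (23.1%), immune (6.25%), mesothelium (14.3%), liver (14.3%), striated muscle (6.67%), brain neuron (14.3%), epidermis (16.7%) and germ cells (7.14%). There, stem and progenitor (75.0%), interstitial cell (83.3%) and Hox genes (69.2%) became called higher, and neuron and glia (31.8%), endothelium (53.3%) and erythroid genes (33.3%) turned higher, uncalled.

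Median domain widths changed side or call as follows. Neuron and glia genes fell below all marked genes at −log10 q of at least 2 (1426 bp) and 5 (957 bp), in the pooled list (1068 bp), at gaps of 500 bp (957 bp) and with 1 replicate left out (459 to 996 bp). That was called without replicate 2 (permutation adjusted p = 0.00154). Enterocyte genes lay below at −log10 q of at least 5 (1480 bp) and were called wider with 1 replicate left out (2054 to 2146 bp), in the pooled list (3581 bp) and at gaps of 3000 bp (3332 bp). The Hox call ended at −log10 q of at least 5 (1794 bp) and at gaps of 500 bp (1571 bp), and the median lay below without replicate 1 (range 1216 to 1946 bp). The junction call ended at −log10 q of at least 5 (2144 bp), and that of the stem and progenitor list in the pooled list and at gaps of 3000 bp (2375 bp in both). Smooth muscle lay below at gaps of 500 bp (1369 bp) and without replicate 1 (range 1360 to 1563 bp), and was called wider in the pooled list (3481 bp) and at gaps of 3000 bp (2812 bp), as were suckling-stage (2936 bp) and housekeeping genes (2886 bp) at those gaps. Endothelium was called narrower without replicate 1 (range 750 to 878 bp) and at gaps of 500 bp (795 bp).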

Other observations

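The test of adult-stage against other enterocyte genes was chosen after the result was seen.

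Marking differed among the Hox clusters, a difference that was not tested. In the A cluster 11 of 11 genes were marked, from Hoxa1 (fold 10.1) to Hoxa13 (4.18), and Hoxa2 had the widest domain of these clusters at 6193 bp. In the B cluster the genes from Hoxb2 to Hoxb9 were marked and Hoxb1 and Hoxb13 were not. Hoxc4, Hoxc5 and Hoxc6 were marked in the C cluster and the genes from Hoxc8 to Hoxc13 were not, and in the D cluster Hoxd1, Hoxd10, Hoxd12 and Hoxd13 were unmarked. These genes were named after their values were seen.

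Distal peaks were most numerous, by nearest protein-coding gene, around Irf2bp2 (10 peaks), Dclk2 (9) and Ezr (8), the gene of the brush border protein ezrin. Among the gene lists, Ephb2, a receptor of crypt cells, had 5, Epcam and Actb 4 each, and Gata4 and Creb3l1 3 each. These genes were likewise named after their values were seen.

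One hypothesis was that distal peaks gather near the transcription factors of the epithelium and the genes of the mesenchyme. Of 1697 distal peaks 15 (0.884%) had a member of these lists as the nearest gene, against a median of 0.668% and a maximum of 3.08% over 1000 shifts (permutation p = 0.310). The share was above the median and below the bound that had been set, so the hypothesis was neither met nor excluded.

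A second hypothesis was that promoters of adult-stage enterocyte genes carry the mark less often at birth than those of other enterocyte genes. In the replicated list 2 of 10 adult-stage and 21 of 22 other enterocyte promoters were marked (two-sided Fisher's exact p = 3.6e-05). The p was 0.0187 in the replicate 1 list (5 of 10 against 20 of 22), 0.00487 in the replicate 2 list (4 of 10 against 20 of 22) and 0.00584 in the pooled list (6 of 10 against 22 of 22), all by Fisher's exact test. Since the hypothesis came from these shares, and the peak lists share reads, the p-values restate the difference and do not test it. The median CpG ratio of the promoters was 0.193 and 0.195. The data hold 1 age, so a change after birth was not tested.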
